A study of Drosophila melanogaster with 12 samples.

How the data were processed

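The study profiled the central nervous system of wandering Drosophila melanogaster larvae of the third instar. Targeted DamID was run with 2 samples each of Dam alone, Dam fused to Scalloped (Sd) and Dam fused to Nerfin-1. In this assay a bacterial adenine methylase is tethered to a protein and marks the GATC sites that the protein comes near. The transgenes were driven by GMR31H08-Gal4 under a temperature-sensitive Gal80. Per the labels, eggs were laid at 25°C, animals were held at 18°C for 4 days, and expression was allowed at 29°C for 24 hours. ATAC-seq (3 samples) and RNA-seq (3 samples) used cells carrying a nerfin-1 GFP reporter and sorted by fluorescence. Per the labels, RNA from sorts of different days was pooled into the 3 RNA samples, so their spread is that between pools.

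Per the submitters' processing notes the genome build was dm6 and the tools were Subread, featureCounts, edgeR, bedtools, Bowtie2 and MACS2; which tool made which file, and its settings, are not given in the sources used here. The authors' deposited ATAC list holds 35494 intervals and their DamID lists hold 4064 distinct Sd peaks and 3649 distinct Nerfin-1 peaks. The DamID lists pair each peak with gene identifiers, which gives 5073 and 4527 rows. The lists carry no height, score or p-value and no value per replicate, and how the replicates and the Dam-only samples entered the calls is not given in the sources used here. The farthest Sd peak lay 4999 bp from a gene and 1 Nerfin-1 peak lay beyond 5 kb, so the DamID lists look limited to the neighbourhood of genes, whereas 4012 ATAC peaks lay more than 5 kb away. The authors' deposited RNA table holds raw read counts per gene for 5135 genes that they kept as expressed, by a rule not given in the sources used here. Its 3 columns are called libraries S1, S2 and S3, since their names could not be tied to replicate numbers; no column of the table was left unmapped to a group (0 columns). Counts over the listed genes came to 43555895 in S1, 44657928 in S2 and 57468071 in S3. These totals leave out genes that were not listed, so they are not the full depth. The lowest listed count was 99, and counting error was not separated from the spread between libraries. The depth of the DamID and ATAC samples is unknown here.

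Gene positions came from a table of the same assembly, with no strand, exons or sequence, so promoters, introns and motifs were not analysed here. The 13922 protein-coding genes on 2L, 2R, 3L, 3R, X and 4 were used. A gene counted as bound when a peak overlapped the gene or 1 kb on either side. Of 8165 gene identifiers in the files, 167 matched no symbol. The identifiers come from an older annotation: 298 protein-coding genes now carry newer identifiers and could not be looked up in the RNA table or in the authors' assignment. In shares over all protein-coding genes they count as not listed, except in the alternative that leaves them out.

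Overlap meant at least 1 bp. Each share was set against 10000 rotations of the list along each chromosome, between the first and last peak of any list (one-sided permutation test, smallest possible p 0.0001). Rotation keeps peak lengths and spacing but takes boundaries off the GATC fragments. Co-occurrence among ATAC peaks was given as an odds ratio with a 95% interval from 2000 bootstrap draws of 1 Mb blocks. Shares carry 95% Wilson intervals, and differences between classes of peaks were tested with Fisher's exact test (two-sided). Listing in the RNA table was compared by a Mantel-Haenszel odds ratio over 10 gene-length strata. RNA levels were computed as counts scaled to 1000000 listed counts per library (CPM), log2-transformed after adding 1, and compared as the difference of medians within the same strata with 10000 permutations (two-sided). For 17 gene lists, the number of members with both peaks was set against 10000 random lists matched on gene length (one-sided), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The RNA table has a single group, so no test of differential expression was run. After seeing the values, the median log2 level in S1 minus the mean of the others was computed for each list and, with at least 5 listed genes, set against the 95% range of 10000 random lists matched on gene length. The p-values of this comparison are left out of the text, since S1 is a single library and genes of a list are not independent. Peaks and neighbouring genes are not independent. The SD of RNA levels covers the spread between pools, and none of the errors covers the spread between animals.

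The groups, tests, gene lists and most alternatives were fixed before the data were examined. The genes named are sd and nerfin-1; members of the 17 lists, in list order, up to 6 with both peaks, 6 with 1 kind and 6 with none; the genes at the 10 longest shared stretches and at the 5 longest peaks found in 1 DamID list only (length replaced the score that the lists lack), taking the overlapped or nearest protein-coding gene; and the 10 highest genes of the RNA table. Exceptions are marked as chosen after their values were seen. Of 245 list entries 244 were tested; the microRNA gene ban was not. Alternatives covered the overlap rule, the longer 50% of each DamID list, the chromosomes used, random placement, wider gene flanks, peaks in open chromatin only, no length matching, the pseudocount and leaving out each RNA library. Added after seeing the data were rotation within 5 kb of genes, ATAC peaks of at least 100 bp, the authors' own assignment of peaks to genes, leaving out genes with newer identifiers, matching lists also on being listed as expressed, and rotating list members together.

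The functions were tested on simulated data. For the overlap test, 2000 independent simulated peaks gave a share 0.695 points from the rotation mean. These peaks had no common grid of boundaries, whereas DamID peaks share GATC sites. A first simulation with a common grid of starts did not pass, since rotation takes peaks off such a grid. The check therefore does not cover the setting of the DamID lists. For the expressed-gene comparison, a simulated odds ratio of 3 over 13000 genes was returned as 3.21, against 4.30 without length strata. For the gene lists, 3.5% of random lists of 20 among 13000 simulated genes passed the threshold. For RNA levels, a simulated difference of 0.5 over 4000 genes was returned as 0.47. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.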

Results

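Binding of Sd and Nerfin-1 was measured in cells of the larval central nervous system driven by GMR31H08-Gal4. Open chromatin and RNA were measured in sorted nerfin-1 GFP cells. The DamID animals were shifted from 18°C to 29°C, while only egg laying at 25°C is given for the sorted cells. Binding is thus set against open chromatin and RNA across cells chosen in different ways and across temperature regimes. Sd is the Drosophila TEAD-family DNA-binding protein and Nerfin-1 is a zinc-finger transcription factor of newborn neurons. The data comprised 2 Dam-only, 2 Dam-Sd and 2 Dam-Nerfin-1 DamID samples, 3 ATAC-seq samples and 3 RNA-seq samples. The DamID and ATAC results were available as 1 peak list per group, without replicate values, and the RNA as counts in libraries S1, S2 and S3 (43555895, 44657928 and 57468071 counts over the listed genes). Positions are on dm6. RNA levels are counts scaled to 1000000 listed counts per library (CPM), as mean ± SD over the 3 libraries.

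The first question was whether Sd and Nerfin-1 occupied the same sites. Both fusion proteins had peaks at both of their own genes. At nerfin-1 (FBgn0028999, 3L, 909112 to 912319) each list held 2 peaks, of which the one from 907660 to 909941 had identical boundaries in both lists. At sd (FBgn0003345, X, 15804370 to 15827682) there were 3 Sd and 2 Nerfin-1 peaks. Both genes were expressed in the sorted cells, nerfin-1 at 2070 ± 371 CPM (SD, n = 3) and sd at 393 ± 20.6 CPM (SD, n = 3). The fusion transgenes contain coding sequence of these genes, so peaks inside them can include reads from the transgene.

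The longest shared stretch, of 13727 bp, lay in sbb (2R, 18303858 to 18317584). It was followed by 10011 bp at erm (2L, 1963706 to 1973716), which encodes a zinc-finger factor of intermediate neural progenitors, and by 9484 bp in gukh (3R). The remaining stretches among the 10 longest lay at Sin3A and Amph, CG10195, Bicra, lola, Ctps and CG45071, CadN, and in a region whose nearest protein-coding gene was CG17048, 17033 bp away. The longest Sd peak without a Nerfin-1 peak, of 10655 bp, lay 6788 bp from its nearest protein-coding gene, Osi21. The next longest were nearest to CG43312 (5524 bp away) and Prat2 (29093 bp away), or lay in E2f1 (peak of 6394 bp) and at EcR and CG14589. Only protein-coding genes were named here, so genes of other kinds may lie closer. The longest Nerfin-1 peak without a Sd peak, of 8134 bp, lay 803 bp from tna. The next longest lay at CG15020 and nAChRbeta1, in sns, at Jupiter and CG14710, and in CG14478.

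Of the 4064 Sd peaks, 2708 (66.6%) overlapped a Nerfin-1 peak, and of the 3649 Nerfin-1 peaks, 2743 (75.2%) overlapped a Sd peak. Rotated lists gave 8.23% (95% range 7.33 to 9.20) and 9.17% (8.14 to 10.3), so the observed shares were 8.10-fold and 8.20-fold higher (permutation test, p = 0.0001 for each, the smallest the rotations can give). The lists shared 4021 kb, 50.4% of the sequence covered by either, and 1446 peaks had identical boundaries in both. With at least 50% of a peak covered, the Sd share was 57.6%, 16.0-fold above rotation, and the Nerfin-1 share was 70.8%, 15.8-fold above. The design has the same 2 Dam-only samples for both fusion proteins. If both lists were called against them, part of the excess may come from these shared controls, which peak lists cannot resolve. Rotation also takes boundaries off the GATC fragments, and how far this adds to the excess was not tested.

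**Figure D1:**
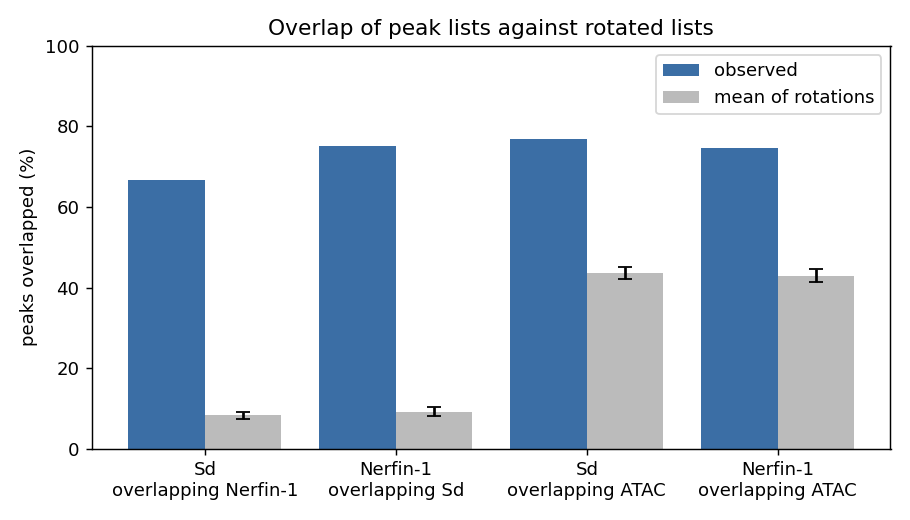
Share of peaks overlapped by at least 1 bp of the second list (y axis, %), for 4 pairs of lists (x axis). Blue bars are observed, grey bars are the mean of 10000 rotations and error bars their 95% range; the Sd and Nerfin-1 lists overlapped at 66.6% and 75.2%, against 8.23% and 9.17% for rotated lists.

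The next question was how the sites related to open chromatin of the sorted cells. The dpn peaks of both lists and the shared stretch at erm lay in open chromatin, the latter over 5 ATAC peaks. By contrast, the Sd peak of 2759 bp in CycE (2L, 15741876 to 15744634) overlapped none. Overall 76.8% of Sd peaks and 74.7% of Nerfin-1 peaks overlapped an ATAC peak, against 43.7% (42.2 to 45.2) and 43.0% (41.4 to 44.6) for rotated lists. These were 1.76-fold and 1.74-fold excesses (permutation test, p = 0.0001 for each, the smallest possible). With at least 50% of a peak covered, the shares were 37.4% and 39.0%, or 4.09-fold and 4.21-fold above rotation.

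Peaks shared by both proteins lay in open chromatin more often than unshared ones. For Sd the shares were 83.2% (95% interval 81.7 to 84.6) of shared and 64.0% (61.4 to 66.5) of unshared peaks, a difference of 19.2 percentage points (Fisher's exact test, p = 9.87e-41). For Nerfin-1 they were 81.1% (79.6 to 82.5) and 55.1% (51.8 to 58.3), a difference of 26.0 points (Fisher's exact test, p = 4.36e-51). Unshared peaks were also shorter, with medians of 780 against 1422 bp for Sd and 1014.5 against 1217 bp for Nerfin-1. With both lists cut to their longer 50% of peaks, the differences were 9.98 and 16.1 points. In that setting a peak that overlapped only a shorter peak of the other list counted as unshared. Of the 35494 ATAC peaks, 2892 overlapped both lists, 1350 only Sd, 682 only Nerfin-1 and 30570 neither, an odds ratio of 96.0 (95% interval 83.3 to 111).

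The lists of genes fixed before the data were examined were then compared for genes bound by both proteins. The E(spl) complex, a cluster of Notch-responsive genes, had both peaks at 9 of 11 genes, among them E(spl)mdelta-HLH, E(spl)mgamma-HLH, E(spl)mbeta-HLH, E(spl)malpha-BFM, E(spl)m2-BFM and E(spl)m5-HLH. E(spl)m3-HLH and E(spl)m4-BFM, side by side in the middle of the cluster, had neither. Axon guidance and adhesion genes had both at 21 of 24, including the receptors robo1, robo2 and fra and the ligands sli, NetA and NetB; robo3 and unc-5 had Sd only, and trio had neither. At sli there were 4 Sd and 3 Nerfin-1 peaks, and its RNA stood at 873 ± 46.1 CPM (SD, n = 3).

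Random lists matched on gene length gave 1.74 E(spl) genes and 12.9 guidance genes, and these were the only 2 of 17 lists past the threshold (permutation test, adjusted p = 0.0017 and 0.0034). E(spl) genes lie within 43.4 kb of 3R (25997621 to 26041008) and share peaks, but with members rotated together the adjusted p was 0.0026 (permutation test). With matching also on being listed as expressed, 16.2 guidance genes came up in random lists and the call was lost (adjusted p = 0.053, permutation test; 0.00068 to 0.024 in the other alternatives). The number of lists past the threshold ranged from 1 to 12 over the alternatives. Some genes are in more than 1 list, so these counts are not of independent lists.

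**Figure D2:**
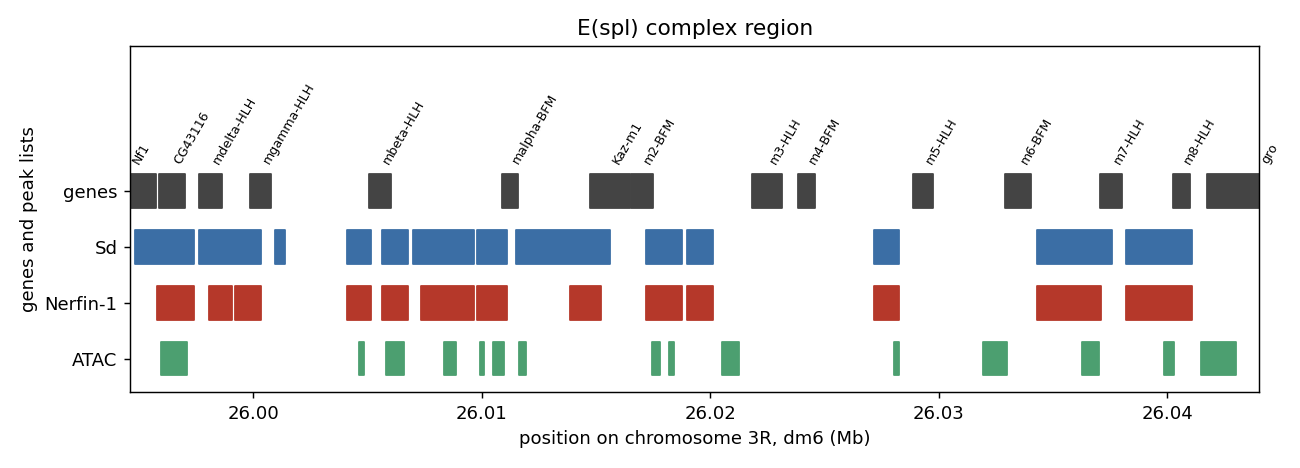
Map of the E(spl) complex, with position on chromosome 3R of dm6 in Mb (x axis) and rows for protein-coding genes, Sd peaks, Nerfin-1 peaks and ATAC peaks (y axis; labels omit the prefix E(spl)). The region held 13 Sd and 13 Nerfin-1 peaks, with none of either at m3-HLH and m4-BFM.

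The calls for the Notch pathway, neuroblast and cell cycle lists depended on the setting. Notch pathway components had both peaks at 10 of 12 genes, among them N, Dl, Ser, Su(H), neur and numb, against 5.82 in matched lists (permutation test, adjusted p = 0.058), and H and Psn had Nerfin-1 only. This list passed under 6 of 7 alternatives, as the guidance genes did (permutation test, adjusted p = 0.00068 to 0.053). Matching on expression moved its matched value only to 6.21. The neuroblast list had both at 7 of 11, including the stem-cell factors dpn, mira, klu and grh, against 3.95 (permutation test, adjusted p = 0.091), and ase, wor, esg and tll had neither. With flanks of 5 kb it had both at 11 of 11, and with the authors' assignment at 10 of 10 (permutation test, adjusted p = 0.0045 and 0.00085; 0.00085 to 0.10 over the alternatives). Cell cycle and growth genes had both at 14 of 24, including Myc, CycE, stg and E2f1, against 8.11 (permutation test, adjusted p = 0.054), and passed under 5 of 7 alternatives. Another 6 of these genes (CycD, Cdk1, Cdk2, PCNA, aurB and fzy) had Sd only and 0 had Nerfin-1 only, a split that did not pass adjustment over the lists (exact binomial test, p = 0.031, adjusted p = 0.53). The test took both kinds as equally likely, while over all genes 1102 had Sd only and 729 had Nerfin-1 only.

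Hippo pathway components had both at 11 of 16 (yki, wts, hpo, ex, Mer and kibra among them) against 6.93, and Yorkie-Scalloped targets at 8 of 10 (Diap1, CycE and Myc among them) against 4.77. These lists share ex, kibra, fj and Mer, and the target list shares CycE, Myc and E2f1 with the cell cycle list. The same genes thus count in several lists. Temporal factors, expressed in sequence by ageing progenitors, had both at 15 of 22 (hth, ey and slp2 among them) against 10.2, and medulla neuron identity factors at 15 of 21 (bsh, run and toy among them) against 10.3. The adjusted p was 0.075 for each of these 4 lists (permutation test), and they passed under 2, 3, 5 and 4 of the 7 alternatives in this order. Both peaks were found at 8 of 14 pan-neuronal genes (7.06 in matched lists), 6 of 13 neurotransmitter genes (5.61), 8 of 12 glial genes (4.77), 8 of 10 ecdysone response genes (5.24) and 5 of 12 ribosomal protein genes (2.50). Hemocyte (3 of 8), muscle (3 of 9) and testis genes (2 of 15) were below their matched values of 3.23, 3.89 and 2.92. None of these 8 lists passed the threshold in the main analysis (permutation test, adjusted p = 0.091 to 0.83).

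**Figure D3:**
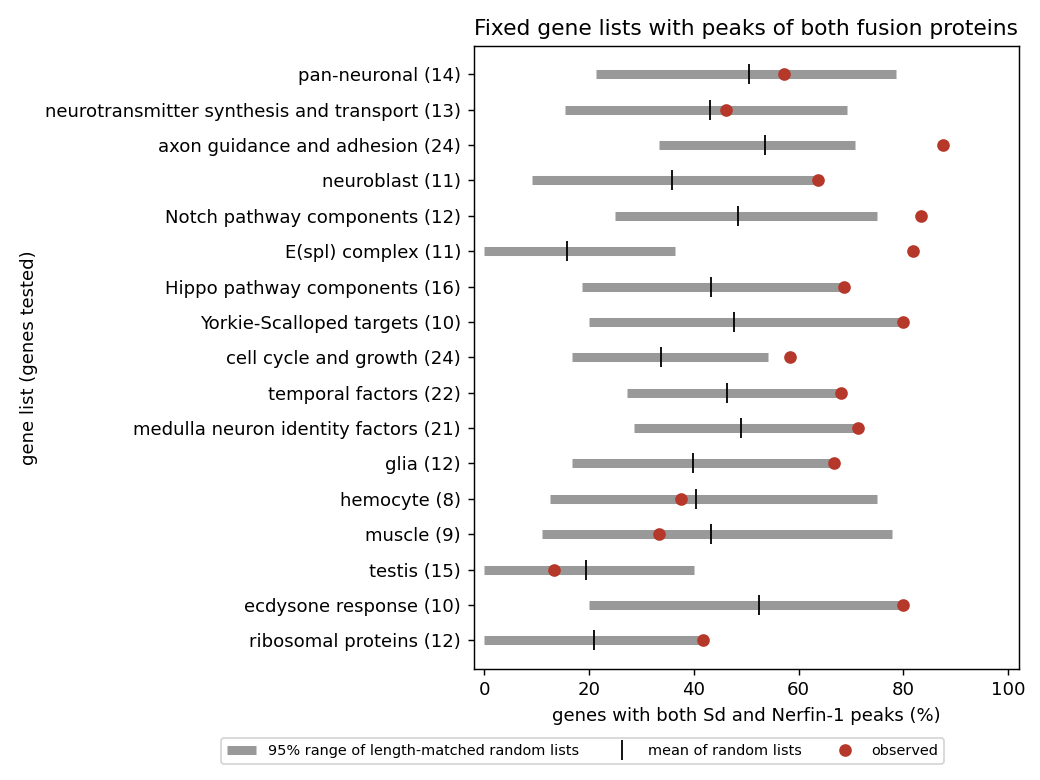
Share of genes with both Sd and Nerfin-1 peaks (x axis, %) for each of 17 gene lists (y axis, genes tested in brackets). Red points are observed, black ticks and grey bars are the mean and 95% range of 10000 random lists matched on gene length; the E(spl) complex (9 of 11) and axon guidance genes (21 of 24) were the lists past the threshold.

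The last question was how occupancy related to expression. Of the pan-neuronal genes 12 were in the expressed table, 1 was not and 1 has a newer identifier. Of the 12, 8 had both peaks, among them elav (1740 ± 50.9 CPM), fne (2408 ± 184 CPM) and nSyb (476 ± 32.8 CPM; SD, n = 3). The listed genes brp (1296 ± 198 CPM) and nrv3 (499 ± 48.9 CPM) had Sd only (SD, n = 3). Syt1 (585 ± 14.5 CPM) and Snap25 (51.6 ± 2.53 CPM) had neither (SD, n = 3). CPM is not divided by transcript length, so genes are ranked here by read counts and not by numbers of transcripts. Highest among the listed genes was pros, a homeodomain factor that ends progenitor divisions, at 11083 ± 1194 CPM (SD, n = 3). It was followed by Act5C, lncRNA:CR42862, fax, 14-3-3epsilon, brat, alphaTub84B, a gene without a matched symbol, Hsp83 and Hsp23. Of other cells' markers, 3 neuroblast genes were listed (such as ase at 47.5 ± 14.0 CPM; SD, n = 3), 7 were not and 1 has a newer identifier. For glia 3 were listed and 9 were not, and for hemocytes 2 and 6. Of muscle genes 0 were listed, 8 were not and 1 has a newer identifier, and of the 15 testis genes 0 were listed. The neuroblast genes dpn, mira, klu and grh, and N and Dl, had both peaks but were not listed as expressed. The rule for listing is not known, and the sorted cells may differ from those of the DamID. The missing listing therefore does not show that these genes were silent where they were bound.

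Across 13922 protein-coding genes, 3857 had both peaks, 1102 Sd only, 729 Nerfin-1 only and 8234 neither. Independent lists of the same sizes would share 1634 genes, a value not adjusted for gene length. Genes with both peaks were longer (median 3852 bp, against 1743 bp with neither), so this value is likely too low. The RNA table listed 58.8% (57.2 to 60.3) of genes with both, 47.6% (44.7 to 50.6) with Sd only, 34.4% (31.1 to 38.0) with Nerfin-1 only and 23.0% (22.1 to 23.9) with neither. Genes with newer identifiers count here as not listed; without them the shares were 60.3% with both and 23.5% with neither. Within gene-length strata the odds ratio of being listed, both against neither, was 3.82 (95% interval 3.51 to 4.17). Among listed genes, those with both peaks had a higher RNA level by 0.30 on the log2 scale within length strata (permutation test, p = 0.0001, the smallest possible). Without length strata the difference was 0.90. Gene positions came without exons, so the strata do not match genes on transcript length. Since CPM is not divided by transcript length either, longer transcripts may account for some or all of the difference of 0.30.

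**Figure D4:**
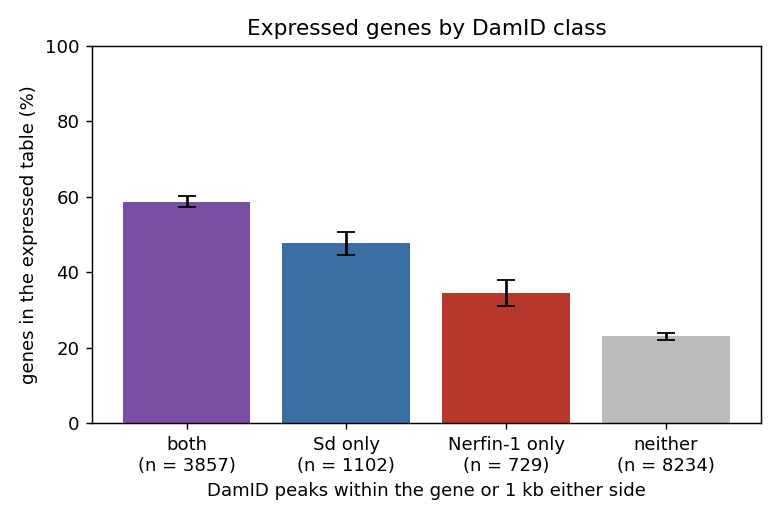
Share of protein-coding genes in the expressed RNA table (y axis, %) by the DamID peaks within the gene or 1 kb either side (x axis), with 95% Wilson intervals. The share was 58.8% for genes with both peaks and 23.0% for genes with neither.

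The values of cell cycle genes in library S1 lay below those in the others. CycA stood at 64.7 CPM in S1, 111 in S2 and 106 in S3, and CycB at 54.8, 103 and 97.1. Over the 15 listed cell cycle and growth genes, the log2 level in S1 minus the mean of the others had a median of -0.65, with 14 of 15 genes below 0, outside the 95% range of length-matched random lists (-0.14 to -0.02). Pan-neuronal genes and temporal factors also lay outside their ranges, on the other side. The median was 0.13 for the 12 pan-neuronal genes, with 1 below 0 (range -0.08 to 0.10), and 0.17 for the 14 temporal factors, with 5 below 0 (range -0.10 to 0.07). The 5 listed E(spl) genes had a median of -0.28, with 4 below 0, and the 11 ribosomal protein genes one of -0.14, with 11 below 0. Both lay inside their ranges (-0.28 to -0.06 and -0.20 to -0.06), and the median of all genes in S1 was -0.08. The medians of the 3 listed glial genes (-0.13) and the 2 hemocyte genes (-0.16) were not set against a range. Some progenitor genes were also low in S1: ase stood at 31.6 CPM against 58.2 in S2 and 52.6 in S3, slp2 at 24.2 against 36.3 and 36.2, and cas at 143 against 305 and 258. By contrast erm was at 182 against 145 and 141, D at 170 against 132 and 136, and hbn at 168 against 134 and 136. The neuroblast gene sna was at 63.6 against 68.3 and 59.9. Of the 14 temporal factors, which include slp2, cas, erm, D and hbn, 5 lay below 0 in S1. The heat-shock gene Hsp70Ba was highest in the same library, at 4952 CPM against 2769 in S2 and 1591 in S3. This comparison of libraries, with cas and Hsp70Ba, was chosen after the values were seen. The ranges take genes as independent and S1 is a single library, so they do not measure the spread between libraries.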

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

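Both results here came from tests chosen after the data were examined, and both concern a difference between the Sd and Nerfin-1 lists. Genes with only Sd peaks were in the expressed table more often than genes with only Nerfin-1 peaks, by 13.2 percentage points (47.6% against 34.4%; Fisher's exact test, p = 2.03e-08). Within gene-length strata the odds ratio was 1.72 (95% interval 1.41 to 2.09), and without genes of newer identifiers it was 1.69 (1.38 to 2.06), so neither gene length nor the newer identifiers account for the whole difference. On chromosome 4, 17 genes had only Sd peaks and 1 had only Nerfin-1 peaks, against 1085 and 728 on the other arms (Fisher's exact test, p = 0.0025, adjusted p = 0.015 over 6 arms). The 17 genes rested on 15 distinct Sd peaks, and the numbers of peaks themselves (58 Sd and 38 Nerfin-1 on chromosome 4) did not pass a test of the difference (Fisher's exact test, p = 0.15, adjusted p = 0.83). The 17 include Eph (559 ± 25.7 CPM) and Ephrin (408 ± 26.0 CPM), a receptor and its ligand in axon guidance, and Cadps (833 ± 41.1 CPM), a factor in vesicle release (SD, n = 3 for each); they were chosen after their values were seen. No other explanation of the first difference was tested, and none of that on chromosome 4.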

How the results depend on the processing

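Alternatives added after seeing the data were rotation near genes, ATAC peaks of at least 100 bp, the authors' assignment of peaks to genes, leaving out newer identifiers, matching lists on expression and rotating list members together. Of 10 results, 9 kept their direction and their side of the threshold under all 57 alternatives run for them, of which the filter at 1 CPM removed no gene and so tested nothing. The excess of the Sd and Nerfin-1 overlaps over rotation ranged from 7.15-fold to 16.0-fold and that of the ATAC overlaps from 1.59-fold to 4.21-fold. The difference in open chromatin between shared and unshared peaks ranged from 9.98 to 19.1 points for Sd and from 16.1 to 26.3 for Nerfin-1. The lowest values came from cutting both lists to their longer 50%, where peaks overlapping only a shorter peak counted as unshared. The odds ratio among ATAC peaks ranged from 94.9 to 117, that of being listed as expressed from 3.39 to 4.76, and the RNA difference from 0.27 to 0.90 (0.29 to 0.31 with each library left out). The number of gene lists past the threshold was the exception. It was 2 in the main analysis and 5 with flanks of 5 kb, 5 with the longer 50% of peaks, 5 with peaks in open chromatin only, 9 with the authors' assignment, 11 with members rotated together, 12 without length matching and 1 with matching on expression. Because some genes are in more than 1 list, these counts are not of independent lists. The cause of the changes was not tested, except that the rise without matching comes from dropping gene length. E(spl) passed under all 7 alternatives (permutation test, adjusted p 0.00068 to 0.0026), and the guidance and Notch lists under 6, with the exception of matching on expression. There the guidance genes had both peaks at 21 against 16.2 in random lists (12.9 in the main analysis) and Notch at 10 against 6.21 (5.82), so for Notch the matched value hardly moved. Cell cycle and temporal lists passed under 5, neuroblast and medulla under 4, glia and Yorkie-Scalloped targets under 3, Hippo under 2, and pan-neuronal, ecdysone and ribosomal lists under 1 each; the neurotransmitter, hemocyte, muscle and testis lists passed under 0. Not run were assignments by transcription start site (no strand was used here), rotation along whole arms (no chromosome lengths) and all tests of the Sd motif (no sequence). No paired analysis was possible because the DamID and ATAC peak lists hold no value per replicate and the RNA has a single group.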

Other observations

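The tests of chromosome 4, of cell-cycle RNA and of the overlap by rotation near genes and by identical boundaries were chosen after the results were seen. The odds ratio among ATAC peaks was planned, but its use against open chromatin as an explanation was written down afterwards; the tests of unshared peaks were set beforehand. Heat-shock genes, which encode chaperones induced by stress, were abundant, with levels that varied between the RNA libraries; no test was run on them. Hsp70Ba stood at 4952 CPM in S1, 2769 in S2 and 1591 in S3, Hsp68 at 2815, 1882 and 866, and Hsp26 at 2910, 1948 and 1217. These genes were chosen after their values were seen, and the Hsp70 copies are near identical, so reads can be shared among them.

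Genes of chromosome 4 were bound by Sd more often than those of the other arms, 56 of 80 (70%) against 35.4% (Fisher's exact test, p = 4.52e-10). Within gene-length strata the odds ratio was 2.27 (95% interval 1.39 to 3.70). For Nerfin-1 the shares were 50% and 32.8%, and the odds ratio within length strata was 1.03 (0.65 to 1.63). Genes of chromosome 4 were also listed as expressed more often, 70% against 35.3% (Fisher's exact test, p = 4.01e-10), with genes of newer identifiers counted as not listed.

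The overlap of Sd and Nerfin-1 was weighed against 3 technical explanations. Open chromatin taken only as present or absent would leave no association among ATAC peaks, where the odds ratio was 96.0. This odds ratio cannot decide on degrees of openness, since longer or more open ATAC peaks may overlap both lists more often. It may also be raised by the 4012 ATAC peaks more than 5 kb from a gene, where the DamID lists hold almost no peaks. Limiting the lists to the neighbourhood of genes gave rotation means of 9.32% for Sd and 10.4% for Nerfin-1, far below the observed shares. Shared Dam-only samples stay open, since how they entered the calls is not known: 35.6% of Sd peaks had the boundaries of a Nerfin-1 peak, which common controls or common binding could both give, and peak lists cannot separate them. Joint binding of the 2 proteins at the same sites remains a hypothesis.

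Unshared peaks were shorter and less often in open chromatin. Peak length may account for part of this: the odds ratio of lying in open chromatin, shared against unshared, went from 2.78 to 1.55 (95% interval 1.31 to 1.82) within deciles of length for Sd, and from 3.50 to 3.07 (2.58 to 3.65) for Nerfin-1. Length alone would have brought both to 1 only if the peaks of a decile were equally long. Lengths still varied within deciles, so the odds ratios that remain cannot exclude it. For Nerfin-1 the deciles moved the odds ratio little. Boundaries set apart by peak calling, as the source of most unshared peaks, would place most of them beside a peak of the other list. However, 10.5% of those of Sd and 11.7% of those of Nerfin-1 lay within 1 kb of one. Such boundaries stay open as the source of some unshared peaks, and no share for rotated peaks was computed. Weaker calls near the threshold and binding by 1 protein alone both stay open and untested, since the lists have no scores.

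The values of cell-cycle genes lay lower in library S1. Gene length, taken as the span in the genome, is argued against: the list median was -0.65 (log2), while length-matched lists gave -0.14 to -0.02. Transcript length was not matched, so this cannot decide on RNA quality. From the shortest to the longest 10% of genes, the median went from -0.17 to 0.04 in S1 and from 0.21 to -0.07 in S3. Scaling to the total leaves the list at -0.56 relative to the median of all genes. Fewer dividing progenitors in the sorts pooled for S1 may be the source, but the neuroblast list gave a median of -0.0080 over only 3 listed genes, with ase lower and erm higher in S1, which decides nothing. Stress of the sorted cells was not tested, as no list of stress genes was fixed beforehand, and the design names no group that separates the libraries, so no biological explanation was tested.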
